A study of Mus musculus with 8 samples.

How the data were processed

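The samples were 3 normal mouse brains and 5 mouse glioblastomas, grouped by the tissue source in the labels and numbered in order within a group, which pairs no samples. RNA was extracted with a column kit and DNase, and libraries were made with the TruSeq RNA kit, per the labels' protocols. Reads were processed with STAR 2.3.0e and Cuffdiff 2.1.1 on the mm9 build, per the submitters' processing notes, which give no roles or settings. The annotation release, filters and strand setting are not given in the sources used here.

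The authors deposited 1 table with a row for each of 30967 RefSeq transcript accessions and library. It holds estimated counts of fragments, per the file headers, and FPKM values that the authors scaled per library. Fragments shared by accessions of a gene were split between them in the deposited estimated counts. For genes with more than 1 accession, 33.3% of the accession values but 97.8% of the sums per gene were whole numbers within 0.01, so the accessions were summed per gene and rounded to whole numbers. Gene symbols came from the NCBI RefSeq table of GRCm38 for 30474 accessions and from GENCODE for 178. The 315 accessions without a symbol held 0.507% of all fragments and were kept under their own identifiers. The reference build differs from that of the authors, so no coordinates are given. A sum that was not whole in at least 1 library was taken as a sign of fragments split with another transcript and marked 608 genes. A status of FAIL marked 46 values of 30 accessions. Counts of near-identical gene copies and of overlapping genes are uncertain.

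Summing gave 23520 features. Library totals ranged from 5490351 to 15564280 fragments, so that 3 fragments corresponded to between 0.193 and 0.546 CPM in a single library. No pair of libraries agreed within sampling noise (chi-square per degree of freedom at least 5.17).

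The main test was edgeR 4.0.16 with TMM factors, the default filter on low counts and the robust quasi-likelihood F test, followed by Benjamini-Hochberg adjustment over 14640 genes with a threshold of 0.05. Standard errors of log2 fold changes were derived from the F statistic, and 95% intervals used 6 degrees of freedom. CPM values are TMM scaled, and log2 CPM used a prior count of 2. A fold against a group with 0 fragments is a bound against 3 fragments over the group. With 1 to 3 fragments the ratio of levels is given with an exact Poisson interval of the lower count. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation, adjusted over 32 lists. The members Cd68, Ly6g, Ighm and Hbb-bt were not analysed here.

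The rule for named genes took Trp53 and Hras; the 10 largest rises and falls among called genes with at least 10 CPM in the higher group and no overlap between groups; and, per list, the 2 called members with the largest change in the majority direction and 1 in the other. Where no member passed, the 2 most abundant were given as values. The groups, tests, lists and rule were fixed before the data were examined. The rule named 95 genes, some of which are not reported here.

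The tests were tested on simulated data. For glioblastoma against normal brain, 200 changed genes were placed among counts drawn from the fitted means, dispersions and library sizes. Among 14430 genes that passed the filter, edgeR recovered 80.8% of 4-fold and 16.7% of 2-fold changes after adjustment, and 2.04% of its calls were false. Without adjustment, 76.0% of the 2-fold changes had a p below 0.05. In the same simulation 23.8% of the calls of DESeq2 were false, and its counts serve only as an alternative. These shares apply to that setting, with 200 changed genes and the same dispersions in both groups. In the data, 71.0% of tested genes were called and 85.1% had the larger SD in tumours.

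Alternatives fixed beforehand were DESeq2 1.42.0, RLE and upper quartile factors, library size only, no filter, a filter of 5 CPM in 3 samples, limma on log2(FPKM + 1) and log2(FPKM + 0.1), each of the 8 libraries left out, and an estimated correlation for the lists. Added after seeing the data were brain 1 and tumour 4 both left out, all libraries thinned to one depth, genes with shared fragments left out, and each accession tested by itself. All 56 splits of the 8 samples into 3 and 5 were also tested. Calculations used R 4.3.3, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.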

Results

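RNA was sequenced from 3 samples of normal mouse brain and 5 mouse glioblastomas. The tumours had been induced with a lentiviral vector that carried an activated Hras oncogene and a short hairpin RNA against p53, and were collected at the clinical endpoint after normal brain had been trimmed away from the fluorescent tumour. The libraries held between 5490351 and 15564280 fragments assigned to transcripts. Brains 1, 2 and 3 held 6315241, 7391165 and 7719196 fragments, and tumours 1 to 5 held 5948893, 5490351, 8027018, 15564280 and 12437291. Nothing in the labels says that the samples of a group came from separate animals, so the p-values below measure the spread between these samples. The brain region of the normal samples is not given in the sources used here.

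The comparison asked how expression in the tumours differs from that in normal brain. The samples were pieces of tissue. For a single gene, a change within cells cannot be told apart from a change in the mix of cell types. Below, rises and falls refer to levels in the whole sample. Among lists of marker genes, 15 of 19 general neuronal genes and 14 of 16 genes of myelinating oligodendrocytes were lower in the tumours, and 29 of 30 cell cycle genes, all 26 extracellular matrix genes, 20 of 21 interferon response genes and 13 of 15 macrophage and monocyte genes were higher. These lists passed a list test with a preset correlation of 0.01, and none passed with an estimated correlation (lowest adjusted p = 0.0602). Of 14640 genes tested, 5426 were higher and 4963 lower in glioblastoma at an adjusted p threshold of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). These were 37.1% and 33.9% of the tested genes, the background for the counts in every list. At least 2-fold changes were found for 4008 genes higher and 3783 lower. The values of the groups did not overlap for 70.6% of the tested genes, against 3.57% expected by chance for 3 samples against 5. The first principal component held 85.8% of the variance and separated the groups. The median SD of log2 CPM per gene was 0.154 among the brains and 0.379 among the tumours, and 85.1% of genes had the larger SD in tumours.

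**Figure D1:**
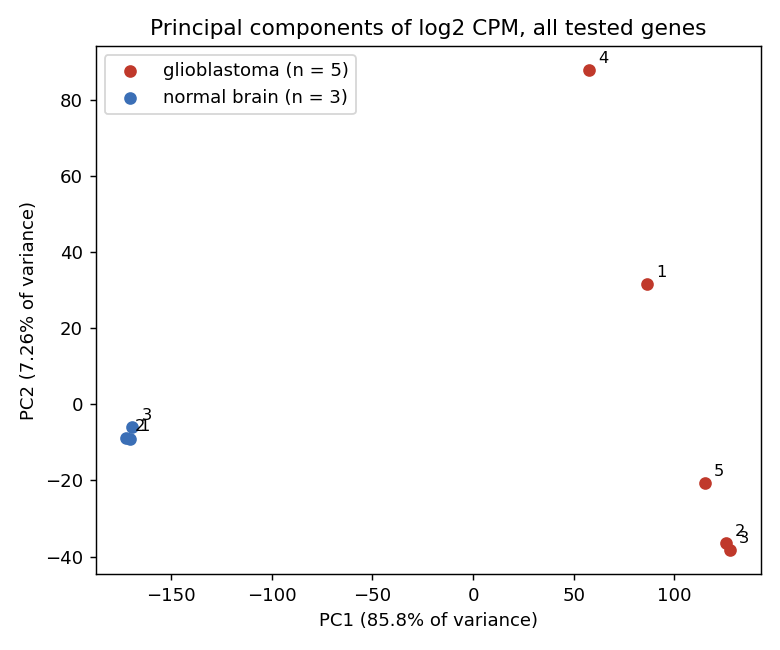
First and second principal components of log2 CPM over all tested genes, with the share of variance on each axis and 1 numbered point per library (blue, 3 normal brains; red, 5 glioblastomas). The brains sit together near -170 on the first component, and the tumours spread between 57.5 and 128 on it, with tumour 4 highest on the second.

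Trp53, the gene targeted by the hairpin, was not detectably lower in the tumours. It was measured at 4.74, 7.21 and 4.91 CPM in brains 1, 2 and 3 and at 2.95, 3.25, 5.92, 2.74 and 5.49 CPM in tumours 1 to 5. The log2 fold change was -0.46 ± 0.35 (SE; 3 brains against 5 tumours; edgeR adjusted p = 0.262), with a 95% interval from -1.32 to 0.39. Trp53 rested on 114 fragments in the brains and 199 in the tumours, and the interval includes both no change and a fall by more than 2-fold. Hras, the oncogene of the vector, rose from 99.5 ± 4.61 CPM (SD, n = 3) to 413 ± 75.1 CPM (SD, n = 5), a log2 fold change of 2.05 ± 0.19 (SE; edgeR adjusted p = 1.9e-05). Fragments from the vector and from the endogenous gene cannot be separated in these counts. The related gene Nras, named after its values were seen, rose by 1.58 ± 0.14 on the log2 scale.

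**Figure D2:**
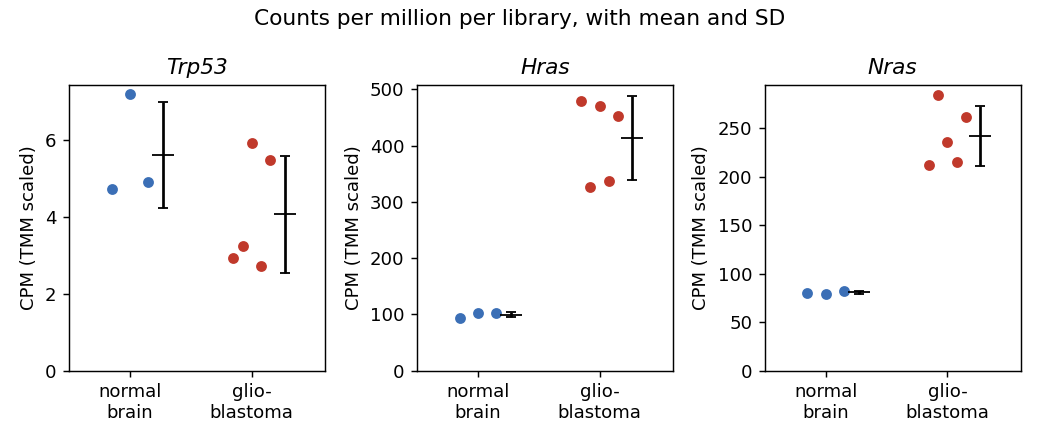
TMM-scaled CPM of Trp53, Hras and Nras in each library (blue, 3 normal brains; red, 5 glioblastomas), each axis from 0, with the mean and SD of each group in black. The groups overlap for Trp53, while every tumour lies above every brain for Hras and Nras.

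Most neuronal genes fell. Of 19 general neuronal genes, 15 were lower and none was higher, and the camera test gave an adjusted p of 4.1e-07 (adjusted p = 0.0602 with an estimated correlation). Snap25, a protein of synaptic vesicle fusion, fell from 2806 ± 523 CPM (SD, n = 3) to 40.0 ± 9.11 CPM (SD, n = 5), and the calcium sensor Vsnl1 fell by 6.23 ± 0.28 on the log2 scale (SE). All 15 genes of glutamatergic neurons were lower (camera adjusted p = 6.4e-07; adjusted p = 0.214 with an estimated correlation), among them Neurod6, a transcription factor of cortical excitatory neurons, with a log2 fold change of -8.21 ± 0.46, and the NMDA receptor subunit Grin2b, with -6.88 ± 0.27. Of 13 genes of GABAergic neurons, 11 were lower (camera adjusted p = 0.000145; adjusted p = 0.214 with an estimated correlation), including the neuropeptide gene Sst (-6.07 ± 0.70) and the vesicular transporter gene Slc32a1 (-5.53 ± 0.36).

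Most genes of mature glia also fell. Of 16 genes of myelinating oligodendrocytes, 14 were lower (camera adjusted p = 0.000145; adjusted p = 0.299 with an estimated correlation), including Mog (-4.37 ± 0.30) and Opalin (-4.30 ± 0.75; -5.00 without tumour 4). Brain 1 had a higher level of this list, at 7.44 mean log2 CPM against 6.32 and 6.43 in brains 2 and 3. Of 14 astrocyte genes, 10 were lower (camera adjusted p = 0.00562; adjusted p = 0.365 with an estimated correlation), including the neurotensin receptor gene Ntsr2 (-4.89 ± 0.39) and the glutamate transporter gene Slc1a2 (-4.04 ± 0.48). Fragments of Slc1a2 were split with another transcript in 3 libraries.

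By the rule that takes the 10 largest falls, Myoc had 0 fragments in the tumours and was at least 174-fold lower against a floor of 3 fragments over the group, or at least 85.5-fold without brain 3. Drd5, a dopamine receptor gene, had 2 fragments in the tumours, and its brain level was 264 times that of the tumours (95% counting interval 73.1 to 2181). Mas1, Igfn1, Slc30a3, Kcnh3, Spink8, Itpka and Hpca had log2 fold changes of -7.58, -7.56, -7.48, -7.33, -7.28, -7.25 and -7.03. Without tumour 4 they were -8.31 for Mas1 and -8.50 for Igfn1, and without tumour 5 it was -8.43 for Spink8. Intervals and floors cover counting error only.

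Most cell division genes rose. Of 30 cell cycle genes, 29 were higher (camera adjusted p = 2.8e-10; adjusted p = 0.214 with an estimated correlation). Cdk1, the kinase that drives entry into mitosis, rose from 0.806 ± 0.575 CPM (SD, n = 3) to 128 ± 40.4 CPM (SD, n = 5). Its partner Ccnb1 had 2 fragments in the brains and stood 341 times higher in the tumours (95% counting interval 94.4 to 2817). Brain 3 held both fragments, and the tumour level of Ccnb1 was 227 times a floor of 3 fragments over all 3 brains.

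All 26 extracellular matrix genes were higher (camera adjusted p = 1.9e-09; adjusted p = 0.214 with an estimated correlation). The metalloproteinase inhibitor gene Timp1 had a log2 fold change of 9.02 ± 0.36. Of 21 genes of the mesenchymal glioblastoma class, 20 were higher (camera adjusted p = 9.1e-08; adjusted p = 0.214 with an estimated correlation), including the galectin gene Lgals3 (8.27 ± 0.49). The mesenchymal list stood at 6.70, 7.15, 7.19, 6.45 and 7.12 mean log2 CPM in tumours 1 to 5, and the macrophage and monocyte list, which shares the member Cd44 with it, at 5.52, 5.99, 6.47, 4.76 and 6.01; their brain means were 2.52 and 1.03. Of 13 genes of the classical class, 7 were higher and 2 lower, and the list did not pass the camera test (adjusted p = 0.0546). Nes, an intermediate filament gene of neural progenitors, rose by 6.70 ± 0.19 and the Notch ligand gene Jag1 by 5.82 ± 0.52, while Elovl2 fell by 3.08 ± 0.53 (3.75 without tumour 4). Of 18 neural progenitor genes, 9 were higher and 1, Hes5 (-3.15 ± 0.96; -5.32 without tumour 4), was lower. Without tumour 4, and with limma on log2(FPKM + 1), 4 were lower, without tumour 2 it was 2, and without brain 3 it was 0. The camera adjusted p of that list was 0.0422, and adjusted p = 0.402 with an estimated correlation. It was 0.0968 without tumour 4 and 0.0742 with scaling by library size only. Vim, in the same list, rose by 6.47 ± 0.20.

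**Figure D3:**
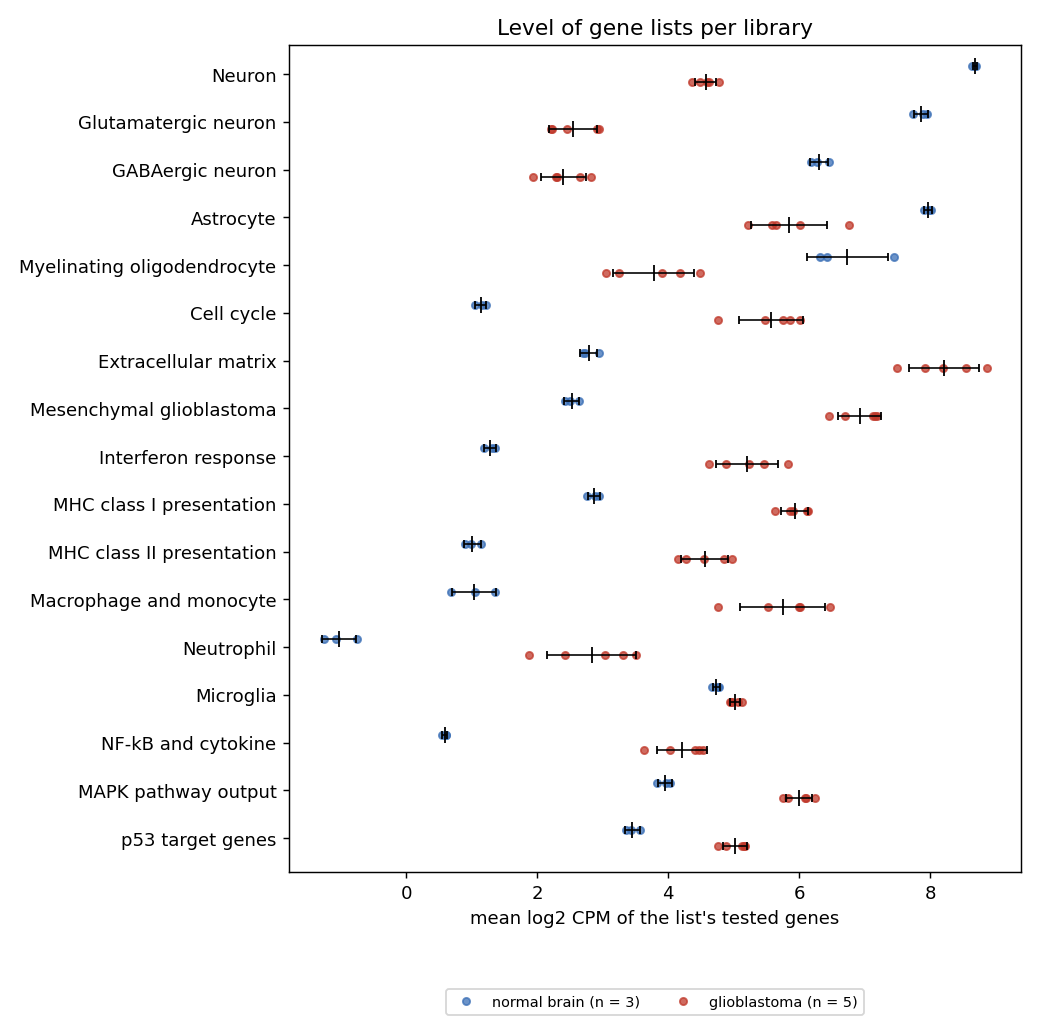
Mean log2 CPM of the tested genes of 17 gene lists in each library (blue, 3 normal brains; red, 5 glioblastomas), with the mean and SD of each group in black. The 3 neuronal lists, the astrocyte list and the myelin list lie lower in every tumour than in every brain, and the other 12 lists lie higher.

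Most interferon and antigen presentation genes rose. Of 21 interferon response genes, 20 were higher (camera adjusted p = 9.1e-08; adjusted p = 0.214 with an estimated correlation). The chemokine gene Cxcl10 rose by 6.55 ± 0.67 (7.47 without brain 2), and Cxcl9, with 0 fragments in the brains, stood at 1.64 ± 0.783 CPM (SD, n = 5) in the tumours. The median log2 fold change of the list was 4.76, or 4.47 with genes at 0 set to their bound. All 15 genes of MHC class I presentation were higher (camera adjusted p = 3.0e-06; adjusted p = 0.214 with an estimated correlation), including H2-K1 (4.63 ± 0.23) and its activator Nlrc5 (5.57 ± 0.44). All 10 genes of MHC class II presentation were higher (camera adjusted p = 0.000145, adjusted p = 0.214 with an estimated correlation), including H2-Ab1 (5.24 ± 0.51). Ciita had 1 fragment in the brains, in brain 3, and stood 58.1 times higher in the tumours (95% counting interval 10.4 to 2295). The tumour level of Ciita was 19.4 times a floor of 3 fragments over all 3 brains. The macrophage and monocyte list stood 4.72 higher in the tumours than in brain (mean log2 CPM).

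Most macrophage genes rose, and microglia genes went both ways. Of 15 macrophage and monocyte genes, 13 were higher (camera adjusted p = 1.7e-05; adjusted p = 0.214 with an estimated correlation). Arg1, an arginine-degrading enzyme of macrophages, rose from 1.21 ± 0.527 CPM (SD, n = 3) to 415 ± 120 CPM (SD, n = 5), and the lectin gene Clec4d, at 0 in the brains, was at least 138-fold higher. Of 12 neutrophil genes, 7 had enough fragments to test, and all 7 were higher (camera adjusted p = 0.00562, adjusted p = 0.214 with an estimated correlation). The list averaged -1.02 log2 CPM in the brains, and a gene so low there can pass the filter only through the tumours. The filter thus favoured higher genes, which the count of 7 and its test do not allow for. With the filter of 5 CPM in 3 samples, 4 were higher. Mmp8 had 0 fragments in the brains, so it passed the filter on low counts only through the tumours. It was at least 56.2-fold higher (37.2-fold without tumour 3), and Mmp9 had a log2 fold change of 6.71 ± 1.15 (6.01 without tumour 5). Of 14 microglia genes, 7 were higher and 3 lower, and the list did not pass (camera adjusted p = 0.334). Itgam rose by 2.68 ± 0.27 and Aif1 by 2.21 ± 0.20, while Siglech fell by 3.64 ± 0.46. Of 22 NF-kB and cytokine genes, 21 were higher and 1, the chemokine gene Cxcl12 (-1.92 ± 0.39), was lower (camera adjusted p = 6.4e-07; adjusted p = 0.214 with an estimated correlation). Lcn2 had 2 fragments in the brains and stood 629 times higher in the tumours (95% counting interval 174 to 5191).

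Of 8 immune checkpoint genes tested, 7 were higher and 1 lower (camera adjusted p = 0.00779; adjusted p = 0.214 with an estimated correlation). Cd274, which encodes the ligand PD-L1, rose by 3.85 ± 0.36, and Pdcd1lg2 had 1 fragment in the brains and stood 108 times higher in the tumours (95% counting interval 19.3 to 4256). Sirpa fell by 2.11 ± 0.72 but shared fragments with another transcript in 7 libraries, and its adjusted p was 0.0966 without brain 1, 0.0677 without brain 3 and 0.0532 without tumour 5. Only 4 of 18 T and NK cell genes and 2 of 9 B cell genes had enough fragments to test. Of these, 3 and 2 were higher, and neither list passed (camera adjusted p = 0.0822 and 0.0825). With at most 1 fragment in the brains, Gzmb, Klrb1c and Cd22 passed the filter only through the tumours. They could not have been called lower. Without tumour 2, without tumour 5 and with all libraries at one depth, Gzmb and Klrb1c had too few fragments to test and 1 T and NK cell gene, Il7r, was higher; Gzmb was also untested without tumour 1 and Klrb1c without tumour 4. Gzmb was at least 9.21-fold higher, and Klrb1c, with 1 fragment in the brains, stood 30.8 times higher (95% counting interval 5.54 to 1218). Cd22 had 1 fragment in the brains and stood 87.8 times higher (95% counting interval 15.8 to 3467), and the antibody joining chain gene Jchain rose by 3.97 ± 0.74 (4.57 without brain 2). Brain 1 held the fragment of Pdcd1lg2 and that of Klrb1c, and brain 3 held that of Cd22. Their tumour levels were 35.9, 10.3 and 29.3 times a floor of 3 fragments over all 3 brains.

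Genes read out from the MAPK pathway, which Ras activates, mostly rose. Of 21, 14 were higher and 5 lower (camera adjusted p = 0.00716; adjusted p = 0.214 with an estimated correlation). Emp1 rose by 7.09 ± 0.29, and the ephrin receptor gene Epha4 fell by 4.12 ± 0.39. The transcription factor gene Fosl1 had 1 fragment in the brains, in brain 3. It stood 336 times higher in the tumours (95% counting interval 60.3 to 13274). The tumour level of Fosl1 was 112 times a floor of 3 fragments over all 3 brains. Of 21 p53 target genes, 14 were higher and 2, Zmat3 and Sesn1, were lower (camera adjusted p = 0.00716; adjusted p = 0.214 with an estimated correlation). Eda2r rose by 5.91 ± 0.42, Gdf15 was at least 16.8-fold higher, and Zmat3 fell by 2.46 ± 0.21. Of 14 immediate early genes, 5 were higher and 7 lower, and the list did not pass (camera adjusted p = 0.409). Atf3 rose by 5.14 ± 0.35, and Npas4, an activity-dependent gene of neurons, fell by 6.15 ± 0.60. Without brain 3, 3 immediate early genes were higher. With the filter of 5 CPM in 3 samples, 4 were lower, and the median log2 fold change of the list went from -0.89 to 0.47. Egr4 had 1 fragment in the tumours, in tumour 1, and its brain level was 216 times that of the tumours (95% counting interval 38.8 to 8530). The brain level of Egr4 was 72.0 times a floor of 3 fragments over all 5 tumours.

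Most called vascular genes were higher. Of 16 endothelial genes, 11 were higher and 2 lower (camera adjusted p = 0.0235; adjusted p = 0.214 with an estimated correlation). Esm1 and Angpt2, both linked to vessel sprouting, rose by 8.62 ± 0.86 and 5.24 ± 0.84 (Angpt2 by 4.49 without tumour 4), and Slco1c1, a thyroid hormone transporter of brain endothelium, fell by 2.54 ± 0.40. Of 12 pericyte and smooth muscle genes, 7 were higher and 2 lower, and the list did not pass (camera adjusted p = 0.1005). Cnn1 rose by 5.78 ± 1.14, Acta2 by 4.50 ± 1.25 (3.33 without tumour 3), and Vtn fell by 1.51 ± 0.26. Without brain 1 or 3 or any of tumours 1 to 4, Vtn was the 1 lower gene of that list. None of the 4 red blood cell genes tested passed, and without tumour 5 Alas2 was higher. Hbb-b1, which shared fragments in 8 libraries, stood at 15.4 ± 12.9 CPM (SD, n = 3) in brain and 35.2 ± 22.1 CPM (SD, n = 5) in tumours, and Hbb-b2 at 2.98 ± 2.25 and 4.25 ± 2.86 CPM (camera adjusted p of the list = 0.578). Without brain 1 their log2 fold changes went from 1.20 and 0.53 to 2.11 and 1.33, and neither passed.

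Of 18 glycolysis and hypoxia genes, 10 were higher and 2 lower (camera adjusted p = 0.0403; adjusted p = 0.397 with an estimated correlation). The carbonic anhydrase gene Car9 rose by 4.92 ± 0.87 (5.69 without brain 1), Adm by 4.27 ± 0.44, and Pfkp fell by 0.57 ± 0.12. Pfkp was the 1 lower gene with library size only and without brain 1, 2 or 3 or tumour 1, 2 or 5. This list no longer passed without tumour 4 (adjusted p = 0.0552) or with shared-fragment genes left out (adjusted p = 0.0816). Of 28 oxidative phosphorylation genes, 3 were higher and 9 lower (4 lower with library size only, 13 without tumour 4; 1 higher without brain 1 or brain 2; camera adjusted p = 0.134), with Sdha at -1.23 ± 0.12, Cycs at -1.18 ± 0.15 and Sdhc at 0.59 ± 0.19. Sdhc lost its call without brain 1 (adjusted p = 0.0505) and without brain 2 (0.0766). Of 17 cholesterol synthesis genes, 6 were higher and 3 lower (camera adjusted p = 0.890), with Fdps at 1.32 ± 0.26. Over all tested genes 37.1% were higher and 33.9% lower, and neither the oxidative phosphorylation nor the cholesterol list passed.

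Lists of glial precursors differed between tumours. Of 12 oligodendrocyte precursor genes, 2 were higher, 2 lower and 8 did not pass (camera adjusted p = 0.824). Without brain 1 or brain 2, 1 was higher, and without brain 1, 2 or 3 or tumour 5, 1 was lower. The median log2 fold change of this list was 0.97, but -0.29 without tumour 4 and -0.25 with limma on log2(FPKM + 1). Vcan rose by 4.04 ± 0.49, Pdgfra by 2.36 ± 0.73, and Neu4 fell by 3.25 ± 0.56. Pdgfra lost its call without brain 1 (adjusted p = 0.0618) and without brain 2 (0.0537). Of 13 proneural class genes, 3 were higher and 10 did not pass (camera adjusted p = 0.991), with Tcf12 at 2.78 ± 0.19. Without tumour 4, 3 proneural class genes were lower and the median log2 fold change went from 0.95 to -0.50, without tumour 2, 1 was lower, and with limma on log2(FPKM + 1), 2 were lower and the median was -0.29. Olig1, named after its values were seen, stood at 93.1, 5.59, 4.16, 266 and 5.98 CPM in tumours 1 to 5 and at 67.8, 45.0 and 43.1 CPM in brains 1 to 3.

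Of 10 choroid plexus and ependyma genes, 5 were lower and 1, the water channel gene Aqp1 (2.75 ± 0.91; 4.92 without brain 1), was higher (camera adjusted p = 0.124). Without brain 1, 2 were lower, and without tumour 1 or tumour 5, 3 were lower. The mean log2 CPM of this list was 5.18 in brain 1 against 2.75 and 2.70 in brains 2 and 3. Kl fell by 5.31 ± 0.85 (4.59 without brain 1 and 6.70 without tumour 3). Folr1 had a log2 fold change of -3.29 ± 1.10 with brain 1 and -1.31 without it (adjusted p = 0.322), and its adjusted p was 0.0536 without tumour 1 and 0.0503 without tumour 5. Aqp1 lost its call without brain 3 (adjusted p = 0.0833), as did Hes5 (adjusted p = 0.0753).

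**Figure D4:**
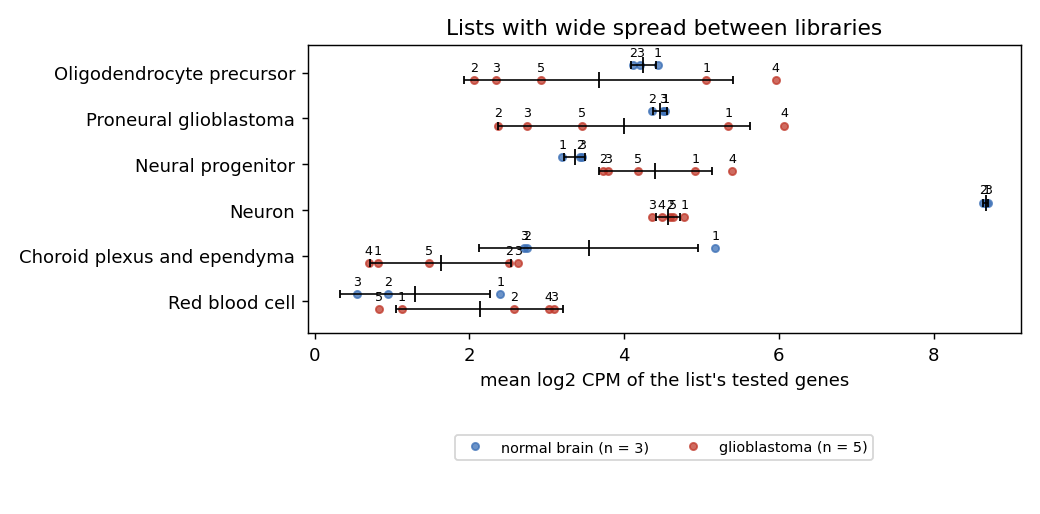
Mean log2 CPM of 6 gene lists in each library, with replicate numbers beside the points (blue, 3 normal brains; red, 5 glioblastomas) and the mean and SD of each group in black. Tumours 1 and 4 stand at 5.06 and 5.96 for the oligodendrocyte precursor list, and brain 1 at 5.18 for the choroid plexus list.

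By the rule that takes the 10 largest rises, Mmp3, Ulbp1, Nppb, Mmp1a, Ccl7, Nipal1, Prl8a9, Clec4d, Cd300lf and Raet1e all had 0 fragments in the brains. The metalloproteinase gene Mmp3 was at least 606-fold higher, Ulbp1, a ligand of the NK cell receptor NKG2D, at least 209-fold, and Nppb at least 196-fold. The bounds were at least 176-fold for Mmp1a, 167-fold for Ccl7, 151-fold for Nipal1, 146-fold for Prl8a9, 136-fold for Cd300lf and 127-fold for Raet1e. Without tumour 5 they were 198-fold for Mmp3, 64.4-fold for Mmp1a and 31.5-fold for Prl8a9. Fragments of Raet1e were split with another transcript in 5 libraries. Prl8a9 stood at 1.40, 9.02, 7.44, 0.874 and 90.0 CPM in tumours 1 to 5, and its adjusted p was 0.0609, 0.0630 and 0.0636 without brains 1, 2 and 3.

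The gene lists were fixed before the data were examined. Of 32 lists, 15 were called higher and 5 lower by camera with a preset correlation of 0.01, and 0 were called with an estimated correlation (lowest adjusted p = 0.0602). Adjusted over the list alone, the counts of higher and lower members were the same as over all genes except for 5 lists. These gave 5 higher and 3 lower for cholesterol synthesis, 2 and 1 for oligodendrocyte precursors, 2 and 8 for oxidative phosphorylation, 14 and 3 for p53 targets, and 8 and 2 for pericytes.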

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

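The tests of tumour content, depth, blood and microglia below were chosen only after the results were seen. The splits of the samples were set before. The second lists for brain 1 concern a pattern already seen, and their bounds were set before those lists were tested. Within the 5 tumours, a gap test for a single distant sample was applied to 126 sets of values, the named genes and the list levels, and marked 5, where chance would mark about 6.3. Mmp1a was far higher in tumour 5, at 6.54 log2 CPM against 2.96 to 3.47 in the others. Fdps was higher in tumour 2, at 5.85 against 4.91 to 5.06. Egr4 had its 1 fragment in tumour 1, at -1.38 log2 CPM against -2.12 in the others, which had 0. Sirpa was lowest in tumour 1, at -2.12 with 0 fragments, against 1.57 to 2.40. H2-Ab1 was lowest in tumour 5, at 3.23 against 4.52 to 4.96.

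By the number of genes called, the real split stood out. The real split gave 10389 calls, and the highest of the other splits gave 653, so that 1 of 56 splits gave as many. At 2-fold, the real split gave 7791 and the highest other 639, again 1 of 56 splits. This is the smallest share that 56 splits can give, and every other split put brains and tumours together in a group. The splits therefore cannot say how many calls chance alone would give. By the number of lists called with the preset correlation, the real split did not stand out. The real split gave 20, 13 of the 56 splits gave at least as many, and the highest other gave 25. The other splits with as many lists had 2 brains (7 splits) or 0 brains (5 splits) in the group of 3, so that brains and tumours were unevenly spread over the groups, while the 30 splits with 1 brain gave at most 14. Such uneven splits keep part of the contrast between brain and tumour, so they cannot decide whether chance gives as many lists. What the count of lists depends on was not tested, and the member counts rest on the tests of single genes.

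Oligodendrocyte precursor genes differed between tumours. The list stood at 5.06, 2.06, 2.35, 5.96 and 2.93 mean log2 CPM in tumours 1 to 5, and at 4.43, 4.11 and 4.21 in brains 1 to 3. Normal brain left in the piece is argued against as the whole source for tumours 1 and 4. The lower of them, 5.06, is above the highest brain by more than 2 SD of the brains (0.165). The neuronal list stood at 4.78 and 4.48 there against 8.64 or more in every brain. Some brain tissue in them stays open, since they stood nearest the brains on the first principal component (86.4 and 57.5 against 115 to 128). Their astrocyte lists were also the highest (6.01 and 6.76 against 5.22 to 5.64). The neuronal list of tumour 4, however, was below those of tumours 2 and 5 (4.59 and 4.63). Sequencing depth is argued against too, since the range over the 5 tumours was 3.76 with all libraries at one depth. The labels give no groups within the tumours, so no biological explanation was tested, and a difference in tumour cell state may remain as a hypothesis.

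Choroid plexus and myelin genes were high in brain 1. Depth is argued against, since the choroid plexus list of brain 1 stayed 2.36 above the higher of the other brains at one depth. Of a second myelin list of 22 genes, 68.2% were at least 1.5-fold above both other brains, against 5.02% of all tested genes, which just passed the bound of 2 in 3 set beforehand, so a piece with more myelinated tissue may explain that part. Of a second choroid plexus list, 13 of 18 genes could be tested. Of these, 46.2% were above, against 5.02% of all tested genes. The value of 46.2% lies between the bounds set beforehand, so choroid plexus tissue in brain 1 stays open by that rule. Both concern the tissue taken for brain 1; the labels give no region, so a biological explanation other than these was not tested.

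Macrophage and neutrophil genes were high in the tumours. The red blood cell list, with 4 tested genes, stood at 2.40, 0.952 and 0.552 mean log2 CPM in brains 1 to 3. The premise, which was not tested, was that all its transcripts come from blood. Blood with unchanged white cells per red cell would then raise the macrophage and neutrophil lists over each brain no more than this list. The lowest excess over any brain was 3.59, 2.61, 2.57, 0.928 and 4.38 for the macrophage list and 2.59, 2.03, 1.71, 0.147 and 3.52 for the neutrophil list in tumours 1 to 5. Set against 2 SD of the red blood cell list in the brains (SD 0.971), a limit chosen with these values known, this argues against such blood for macrophage genes of tumours 1, 2, 3 and 5 and for neutrophil genes of tumours 1, 2 (narrowly) and 5; blood cannot be told apart from other sources for macrophage genes of tumour 4 and neutrophil genes of tumours 3 and 4, where the excess stayed within that limit. A larger share of resident microglia with unchanged expression is argued against. The microglia list had a median log2 change of 0.65 (SD of members 1.63) against 5.16 for the macrophage list. Microglia genes went both ways, and this comparison cannot speak to microglia with changed expression, which were not tested. Entry of myeloid cells, or blood with more white cells, may also remain as untested hypotheses.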

How the results depend on the processing

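The alternatives with brain 1 and tumour 4 both left out, all libraries at one depth, shared-fragment genes left out and each accession by itself were chosen after seeing the data. No paired analysis was possible because the labels give no replicate numbers. Over the 20 alternatives, genes higher ranged from 4796 to 5893 and lower from 4409 to 5464, and at 2-fold from 3387 to 4501 and from 3298 to 4170, all within 1.5 times of the reported counts. Calls shared with each alternative that tests genes had the same direction in all of them. The share of called genes that were higher lay between 50.3% and 57.2%. Upper quartile factors and library size only moved the median log2 fold change of all genes from 0.06 to 0.18 and 0.20. Trp53 stayed below 0 and did not pass (log2 fold change -0.62 to -0.24, adjusted p 0.125 to 0.635), and Hras stayed higher and passed (2.01 to 2.19, highest adjusted p 0.000265). Of 1737 values of the other 93 named genes, 1719 kept direction and side of the threshold, 18 of 7 genes lost their call and 0 reversed. Alternatives in which a gene was not tested or had no adjusted p are not among these values. Most of these genes were chosen for large changes among called genes, so their stability does not speak for the other calls. DESeq2 gave no adjusted p for Mmp1a and Folr1.

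With an estimated correlation the called lists no longer passed. The adjusted p was 0.0602 for Neuron, 0.299 for Myelinating oligodendrocyte, 0.365 for Astrocyte, 0.397 for Glycolysis and hypoxia, 0.402 for Neural progenitor, and 0.214 for Cell cycle, Endothelial cell, Extracellular matrix, GABAergic neuron, Glutamatergic neuron, Immune checkpoint, Interferon response, Macrophage and monocyte, MAPK pathway output, Mesenchymal glioblastoma, MHC class I presentation, MHC class II presentation, Neutrophil, NF-kB and cytokine, and p53 target genes. Neural progenitor also lost its call with library size only (0.0742) and with brain 1 and tumour 4 left out (0.131), and ranged from 0.0278 to 0.0968 with 1 library left out. Glycolysis and hypoxia lost it with shared-fragment genes left out (0.0816), with a range of 0.0229 to 0.0552. Classical glioblastoma passed at one depth (0.0485) and ranged from 0.0375 to 0.106. The causes were not tested. Over the 500 most variable genes, the first component held 91.8% and the median SD was 0.315 in brain and 0.740 in tumours, by the choice of variable genes. Low fragment counts left most T, NK and B cell genes untested. With all libraries at one depth, 14318 genes were tested, 5250 were higher and 4848 lower.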

Other observations

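The test of symbol starts and the single genes below were chosen after the data were seen. Gene symbols were grouped by their first 3 letters, and for each of the 272 starts with at least 10 tested genes the counts of called members were tested against all tested genes (Fisher's exact test, one-sided, adjusted over both directions of all starts). A start can mix unrelated genes, and its members are not independent. Of the 272 starts, 22 passed for higher and 15 for lower genes. The 5 with the smallest p for higher genes were Psm (43 of 49 higher, 1 lower; adjusted p = 1.4e-10), Rpl (34 of 39, 1 lower; adjusted p = 2.3e-08), Ifi (23 of 26, 0 lower; adjusted p = 1.1e-05), Cen (19 of 22, 1 lower; adjusted p = 0.000287) and Nup (20 of 24, 1 lower; adjusted p = 0.000287). Rpl genes have many near-identical copies in the genome and their counts are uncertain. The 5 for lower genes were Kcn (55 of 75 lower, 6 higher; adjusted p = 8.6e-10), Cam (17 of 20, 2 higher; adjusted p = 0.000287), Cac (21 of 27, 1 higher; adjusted p = 0.000287), Gri (17 of 21, 0 higher; adjusted p = 0.000710) and Zfp (157 of 352, 61 higher; adjusted p = 0.000794). With DESeq2, RLE, upper quartile and library size scaling these 10 starts passed, except that Zfp had an adjusted p as high as 0.0928.

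The single genes included Cdkn2a, a tumour suppressor locus upstream of p53 and Rb, which stood at 0.507, 0.289 and 0.818 CPM in brains 1 to 3 and at 220, 221, 221, 349 and 231 CPM in tumours 1 to 5 (log2 fold change 8.80 ± 0.37 SE). The p53 targets Cdkn1a and Mdm2 had log2 fold changes of 3.24 ± 0.34 and 1.53 ± 0.15, while Trp53 itself was not detectably changed. Hmga2, a chromatin protein gene of embryonic tissue, stood at 0.300 ± 0.0343 CPM (SD, n = 3) in brain and 339 ± 162 CPM (SD, n = 5) in tumours. Xist, expressed from the inactive X chromosome, stood at 296, 355 and 0.682 CPM in brains 1 to 3 and at 219, 0.902, 144, 0 and 0.0808 CPM in tumours 1 to 5. The Y-linked gene Ddx3y stood at 0.338, 0 and 123 CPM in the brains and at 0.465, 156, 0, 145 and 215 CPM in the tumours, so both patterns occurred in each group. Sex, which the labels do not give, was not a term in the tests.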
